A study of Mus musculus with 65 samples.

How the data were processed

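Nascent transcription was measured by PRO-seq, in which RNA polymerases in isolated nuclei extend their transcripts with a biotin-tagged nucleotide so that newly made RNA can be pulled down and sequenced. The 65 samples were MEL cells, a mouse erythroleukemia line, that carried the corepressor Mtg16 (gene Cbfa2t3) fused to an FKBP degradation tag and an HA tag. Per the labels' protocols, the cells received 250 nM dTAGV1, a molecule that sends FKBP-tagged proteins to the proteasome (called the degrader here), 10 µM A485, an inhibitor of the acetyltransferases p300 and CBP, or 5 nM LBH589 (panobinostat), an inhibitor of histone deacetylases. The samples formed 23 groups in 4 experiments, called here the time course (degrader and its washout), the A485 series, the LBH589 series and the LBH589 washout series. Washout in the time course meant 2 h of degrader followed by washing and a return to medium. The cells of the LBH589 washout series likewise had 2 h of degrader before washout, and received LBH589 at a time the labels do not give.

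Each experiment came with a table of genes and a table of dREG sites, which are transcribed regulatory elements recognised from run-on data, so that there were 8 tables. Per the labels, the values the authors deposited in all 8 tables were DESeq2-normalized counts, a signal that is never negative. The submitters' processing notes name Bowtie2 2.2.2, SAMtools 1.16.1, bedtools, HOMER, featureCounts 2.0.1 and DESeq2 1.46.0, and the builds mm39 and dm3. The role of each tool, strand use, filters and any part dm3 played in the scaling are not given in the sources used here. Every value came out as a whole number of reads, within a tolerance of 0.1, once it was divided by the smallest step of its library, so that the depth of each library could be recovered. The median ratio of each library to the geometric mean of its experiment's libraries lay between 0.999 and 1.04 in all 8 tables. A change shared by most genes would therefore be invisible, and every change below is relative to the typical gene of the same library. Tables were normalized separately, and tests were made only within a table.

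The gene tables held 25857 transcripts of 15020 gene symbols. Each symbol was represented by its transcript with the highest mean over the 4 experiments. Of the 7011 symbols with more than 1 transcript, 331 had a lowest transcript under 0.5 times the highest, and reads of overlapping genes or close paralogs, such as histone genes, could be split between them. In the reference gene table (assembly GRCm38.p6), 15007 symbols were found, which served for names and gene lengths only. The time course had 23877 dREG sites and the other experiments 29632, with coordinates in mm39 per the submitters' notes. No mm39 annotation was used here, so the gene context of the sites is not given.

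A pair of problems with the labels affected the time course. For 5 libraries (degrader for 1 h and for 2 h) the library name said degrader while the title and treatment label said A485. They were analysed as the library name gives them, and are called the libraries labelled degrader 1 h and degrader 2 h. The gene table of the time course had 22 library names but 21 columns with values. Read as named, its column for 30 min washout replicate 3 correlated at r = -0.48 with the dREG column of the same name and at 0.76 with the next library, 1 h washout replicate 1, over 1406 gene and site pairs. For the later columns this check did not decide: the column 1 h washout replicate 1 was at 0.68 as named and 0.67 with the next library. The columns 1 h washout replicate 2 and 2 h washout replicates 1 and 2 were at 0.47, 0.56 and 0.55 as named and at 0.56, 0.56 and 0.54 with the next, while their best match was degrader 15 min replicate 2 (0.62, 0.61 and 0.63). The ratio of gene reads to dREG reads ran from 7.8 to 13.74 as named and from 7.8 to 10.08 with these columns moved by 1 place. Gene columns whose library was not settled were therefore left out of the gene comparisons (2 columns), and the 2 h washout columns were used as a group without replicate numbers, since either reading puts them in that group. A further per-sample column, empty in the file, was not used in any step (1 column). The gene comparisons of the time course rested on 19 libraries (30 min washout 2, 1 h washout 1, 2 h washout 2) and the dREG comparisons on 22.

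Features with a mean of at least 10 were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend) on log2(value + 1), in a model of all groups of a table, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Fold changes are on this log2(value + 1) scale, which understates the change of low genes. Each fold change is given with its standard error (SE) from that model, and group means are given with their standard deviation (SD). The effect of A485 on the response to the degrader was tested as an interaction, the change of both agents against A485 minus the change of degrader against DMSO. The libraries are separate samples by their labels, but no label says that they came from separate cultures, so that p-values measure only the spread between these samples, which may be technical. No pair of libraries of the same group agreed within counting noise (lowest chi-square per degree of freedom 1.49).

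Before the data were examined, the groups, the comparisons, the tests, the alternatives to be tried and the rule for named genes were fixed. That rule takes Cbfa2t3, the 6 largest rises and falls in each of 7 main comparisons (3 in the others, and 2 for dREG sites) among calls with a mean of at least 50 and no overlap between the groups, up to 4 members of each gene list with the smallest adjusted p, and 10 genes called in the same direction after 30 min in the time course and 1 h in the A485 series. Predicted and unnamed models were left out. The 20 gene lists, with 569 genes, cover erythroid and heme genes, megakaryocyte genes, granulocyte and macrophage genes, mast cell and basophil genes, lymphoid genes, stem and progenitor genes, neuronal and epithelial genes, the SCL/GATA1 complex and blood transcription factors, the MTG family and corepressor partners, acetyltransferases with deacetylases and bromodomain proteins, cell cycle genes, cyclin-dependent kinase inhibitors and p53 targets, Myc targets and ribosome biogenesis, immediate early genes, JAK-STAT feedback and cytokine signalling, NF-kB and interferon genes, TGF-beta and Wnt feedback, Id, Hes and Notch genes, heat shock genes, and unfolded protein and amino acid stress genes. Of these genes, 104 were not analysed here. Each list with at least 5 measured members was set against the other genes with limma's camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over the 20 lists) and again with a correlation estimated from the data. Genes called higher after 30 min of degrader in the time course, and after 1 h in the A485 series, formed a further pair of lists that were read only in other experiments.

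The alternatives were edgeR 4.0.16 (quasi-likelihood test on the recovered reads, with the authors' size factors), a pseudocount of 5, no filter on low values, TMM scaling, the replicate number as a block, leaving out each library in turn, and leaving out the 5 libraries with conflicting labels. Added after seeing the data were fits with every time-course gene column as named, and fits without 3 doubted time-course libraries (15 min replicate 2, 30 min replicate 3 and 30 min washout replicate 3). Under TMM the median of all genes moved by less than 0.1 in every comparison.

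The tests were run on simulated counts drawn from the real libraries' means and depths, with known changes in a random set of features. For degrader 30 min in the time course, limma called 41.9% of genes changed by 0.5 on the log2 scale, 90.2% of those changed by 1 and 98.5% of those changed by 2, with 6 unchanged genes called of 12720 features simulated. For degrader 1 h in the A485 series these shares were 79%, 92.8% and 100%, for the interaction at 1 h 71.2%, 87% and 94.9%, and for LBH589 at 1 h 87.3%, 100% and 100%. For the LBH589 washout they were 34.9%, 84.3% and 98.5%, and for the 2 h washout 35.3%, 82% and 97.2%. At dREG sites, a change of 1 was recovered for 36.2% of sites for degrader 2 h in the time course, 61.4% for degrader 1 h in the A485 series and 71% for LBH589 at 1 h, so that many changes of this size at sites were missed in these simulations. Of 100 unchanged lists per comparison, between 0 and 2 passed an unadjusted 0.05 in camera. The counts were simulated without correlation between genes, so this result cannot tell whether camera's preset correlation is high enough for the real lists. In the real data, 23 calls of fixed lists were lost with an estimated correlation.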

Results

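PRO-seq libraries were collected from MEL erythroleukemia cells in which the tagged corepressor Mtg16 could be removed within minutes and allowed to return, to ask how this protein establishes and maintains repression. The time course held 8 groups: DMSO, degrader for 15 min, 30 min and 1 h (3 libraries each), degrader for 2 h (2 libraries), and washout after 2 h of degrader for 30 min (3 libraries), 1 h (2 libraries) and 2 h (3 libraries). The A485 series held 10 groups: DMSO, and 15 min, 30 min or 1 h of degrader, of A485 or of both, with 3 libraries each except A485 for 30 min and both agents for 30 min, which had 2. The LBH589 series compared DMSO with 30 min and 1 h of LBH589 (3 libraries each). The LBH589 washout series held 30 min and 1 h of washout after 2 h of degrader, in cells that also received LBH589 (3 libraries each). Depth is given in units of 1e6 recovered reads per library. Gene tables held 16.2 to 62.4 in the time course, 7.45 to 62 in the A485 series, 28.1 to 44.8 in the LBH589 series and 13.5 to 29.1 in the LBH589 washout series. The dREG tables were shallower, with 1.97 to 6.96, 0.858 to 7.63, 2.77 to 4.63 and 1.49 to 3.51 in the same order.

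Cbfa2t3, the gene of Mtg16 itself, was transcribed more with every time of degrader treatment. In the time course its normalised read count was 23810 ± 4797 in DMSO (SD, n = 3), 86130 ± 56090 after 15 min (SD, n = 3) and 128400 ± 31710 after 30 min (SD, n = 3). The libraries at 15 min held 58870, 150600 (replicate 2, doubted below) and 48880, and without replicate 2 the log2 change against DMSO was 1.19. Those at 30 min held 112100, 108200 and 165000 (replicate 3, also doubted below). Cbfa2t3 reached 156600 ± 2880 after 1 h (SD, n = 3) and 169500 ± 8909 after 2 h (SD, n = 2). After washout it was 161300 ± 6075 at 30 min (SD, n = 2), 126900 in the 1 library at 1 h and 110100 ± 1289 at 2 h (SD, n = 2). In the A485 series it went from 11270 ± 957 in DMSO to 17350 ± 226, 28100 ± 579 and 50990 ± 1651 after 15 min, 30 min and 1 h of degrader (SD, n = 3 each). With A485 alone it fell to 5339 ± 460 (SD, n = 3), 2564 ± 319 (SD, n = 2) and 662 ± 212 (SD, n = 3) at the same times. With both agents it was 6482 ± 136 (SD, n = 3), 4619 ± 375 (SD, n = 2) and 4505 ± 382 (SD, n = 3). LBH589 lowered it from 51040 ± 1230 to 30600 ± 1740 at 30 min and 23410 ± 1408 at 1 h (SD, n = 3 each). In the washout series it was 59330 ± 1411 at 30 min and 46860 ± 1513 at 1 h (SD, n = 3 each). Levels are not comparable between experiments, which were normalized separately.

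**Figure D1:**
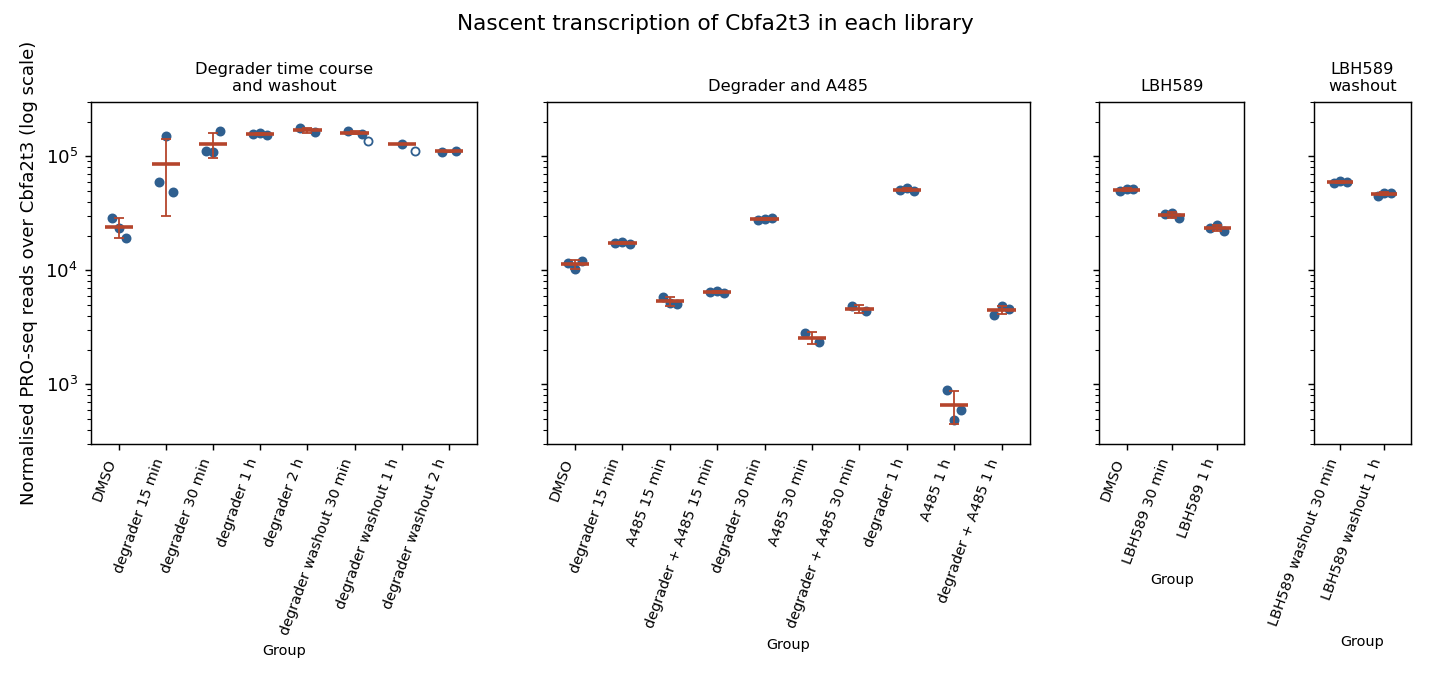
Normalised PRO-seq reads over Cbfa2t3 (log axis) in each library, by group, in the 4 experiments. Filled points are libraries used in the gene comparisons, open points the 2 time-course columns left out, red lines the group means and red whiskers the SD; in the A485 series the means run from 662 with A485 for 1 h to 50990 with degrader for 1 h.

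The direction of Cbfa2t3 bears on the 5 libraries whose title and treatment label said A485 while the library name said degrader. The libraries labelled degrader 1 h and 2 h in the time course had Cbfa2t3 above DMSO by 2.74 ± 0.29 and 2.85 ± 0.32 on the log2 scale (SE, n = 3 and 2 against 3, limma adjusted p = 4.78e-06 and 1.53e-05). In the other series, 1 h of A485 changed it by -4.13 ± 0.11. Across the 12497 genes tested in both experiments, the fold changes of the library group labelled degrader 1 h correlated with those of degrader 1 h in the A485 series at r = 0.64 and with those of A485 1 h at r = -0.21 (Spearman rho 0.45 and -0.07). For degrader 2 h these values were 0.51 and -0.26 (rho 0.28 and -0.19). These correlations are across genes, which are not independent replicates.

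Some time-course libraries stood apart from their own group. At the 2000 most variable dREG sites, 3 of 22 libraries had deviations that correlated below 0 with the other libraries of their group. They were degrader 15 min replicate 2 (mean r = -0.21), degrader 30 min replicate 3 (-0.25) and 30 min washout replicate 3 (-0.23). The lowest of the other libraries was at 0.08. In the gene table, degrader 15 min replicate 2 (-0.36) and degrader 30 min replicate 3 were below 0, 2 of 18 libraries with a partner. The numbers of called genes and sites of the time course are therefore also given without these 3 libraries, a choice made after seeing the data. Of the comparisons made, only degrader 15 min and 30 min against DMSO use any of them. In the others the fold changes stay the same, and only the spread shared by all groups of the fit changes.

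**Figure D2:**
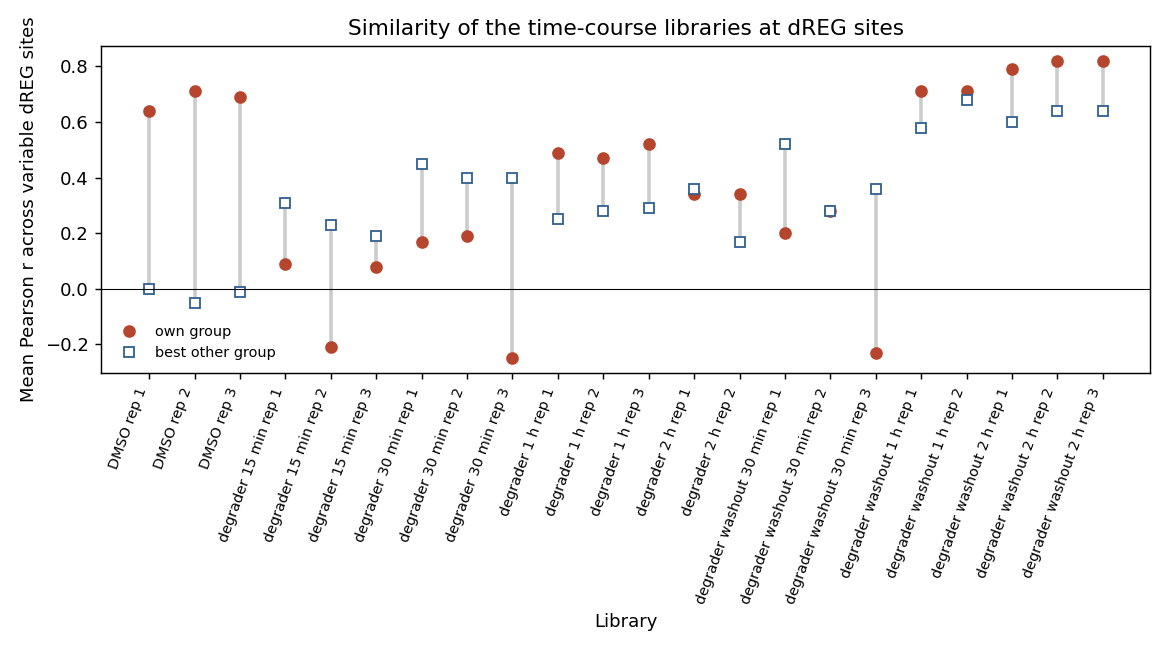
Mean Pearson r (y axis) of each time-course library (x axis) with the other libraries of its own group (filled circles) and with the best other group (open squares), over the 2000 most variable dREG sites, after the mean of all libraries was subtracted. Only 3 of the 22 libraries lie below 0 with their own group, at -0.21, -0.25 and -0.23.

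The first question was which genes change when Mtg16 is removed. After 30 min of degrader in the time course, genes of red cell and platelet differentiation rose together. Hemgn, a nuclear protein of erythroid cells, rose by 2.24 ± 0.14 on the log2 scale (SE, limma adjusted p = 5.41e-08), from 565.7 ± 35.4 to 2708 ± 518.5 normalised reads (SD, n = 3 each). Gypc, which encodes a glycophorin of the red cell membrane, rose by 1.84 ± 0.16 and Alas2, the first enzyme of erythroid heme synthesis, by 1.48 ± 0.13. Itgb3, the platelet integrin beta 3 chain, rose by 2.08 ± 0.16 and F2rl2, a protease-activated receptor, by 1.57. The largest rises were in Il1b, the cytokine interleukin-1 beta (3.14 ± 0.25, from 18.7 ± 6.09 to 172 ± 53.3, SD, n = 3 each) and Slfn14 (2.74 ± 0.26). Next came Acoxl (2.65 ± 0.26), Kcne3, a potassium channel subunit (2.55), Msmb (2.52) and the transporter gene Slc22a4 (2.44 ± 0.42).

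Falls at 30 min were smaller. They were led by the zinc finger genes Zfp970 (-1.97 ± 0.45) and Zfp971 (-1.29), Sema4a (-1.26 ± 0.32), Fbp2, which encodes a fructose bisphosphatase (-1.25 ± 0.39), Anxa2, which encodes annexin A2 (-1.25 ± 0.33), and Arhgap9 (-1.19 ± 0.17). In all, limma called 1764 of 12720 genes, 1106 higher and 658 lower (n = 3 each), and edgeR called 1680. Without the 3 doubted libraries the count was 2679, 1552 higher and 1127 lower. The count fell to 1150, 1042 and 972 when DMSO replicate 1, 2 or 3 was left out, and to 917 without the 5 libraries with conflicting labels.

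Of the 20 gene lists, 3 rose at 30 min. Among 38 measured erythroid and heme genes, 27 rose, 0 fell and 11 did not pass (33 rose when adjusted over the list alone, median log2 change 0.72, camera adjusted p = 1.79e-22). Among 16 megakaryocyte genes, 11 rose, 1 fell and 4 did not pass (12 and 1 adjusted over the list alone, median 0.52, adjusted p = 3.2e-06). Plek, a platelet signalling protein, rose by 1.09 and Fli1, a transcription factor of this lineage, by 0.35. Both lists kept their call with an estimated correlation. Among 24 genes of the SCL/GATA1 complex and other blood transcription factors, 9 rose, 2 fell and 13 did not pass (11 and 2 adjusted over the list alone, median 0.24, adjusted p = 0.00196). That call was lost at adjusted p = 0.143 with an estimated correlation. Members that rose were Lyl1 (1.03 ± 0.08), Gfi1b, a repressor of erythroid and megakaryocyte cells (1.12 ± 0.14), Nfe2 (0.72) and Runx1 (0.60).

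Several lists passed in none of the 7 main comparisons, and their values at 30 min of degrader were as follows. Of 16 measured genes of the MTG family and its corepressor partners, 2 were higher and 1 lower (2 and 2 adjusted over the list alone, adjusted p = 0.805). Of 32 acetyltransferases, deacetylases and bromodomain proteins, 1 was higher and 2 lower (0 and 0 adjusted over the list alone, adjusted p = 0.651). The cyclin-dependent kinase inhibitors and p53 targets had 1 of 21 higher and 0 lower (1 and 0 adjusted over the list alone, adjusted p = 0.209). Id, Hes and Notch genes had 0 of 12 on either side (also 0 adjusted over the list alone, adjusted p = 0.97). Mast cell and basophil genes had 1 of 6 higher (2 adjusted over the list alone, adjusted p = 0.203). Neuronal and epithelial genes had 2 of 9 higher and 1 lower (the same adjusted over the list alone, adjusted p = 0.296). For lists outside a call, median, mean and test could point apart: granulocyte and macrophage genes had a median of -0.14 and a mean of 0.16 at 30 min, with camera's direction up (adjusted p = 0.805). In the called lists all 3 had the same sign.

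After 15 min Il1b was already 2.61 ± 0.25 higher (118.6 ± 34.8 against 18.7 ± 6.09, SD, n = 3 each), Msmb 2.60 and Kcne3 2.27, and Dmwd had the largest fall (-0.84). limma called 881 genes, 749 higher and 132 lower (edgeR 851). The count was 3533 (1790 higher, 1743 lower) without the 3 doubted libraries and 587 without DMSO replicate 2. At 1 h the blood group gene Art4 rose by 3.60 ± 0.42 (107.4 ± 10.2 against 8.11 ± 2.26, SD, n = 3 each) and Slfn14 by 3.18 ± 0.26, and Dmwd fell by 1.53 ± 0.16. There, limma called 1435 genes, 1034 higher and 401 lower (edgeR 1430), or 3842 (1918 higher, 1924 lower) without the doubted libraries. None of those is in this comparison, so its fold changes were the same and only the spread shared by the fit changed.

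By 2 h of degrader, Art4 was 3.74 ± 0.47 higher (117.6 ± 2.78, SD, n = 2, against 8.11 ± 2.26, SD, n = 3). Epb42, which encodes band 4.2 of the red cell membrane skeleton, was 2.98 ± 0.48 higher (690.9 ± 11.8, SD, n = 2, against 89.3 ± 28, SD, n = 3). Slc22a4 (2.91 ± 0.47), the adenylate kinase gene Ak8 (2.90 ± 0.29), Cbfa2t3 (2.85 ± 0.32) and Acoxl (2.81 ± 0.29) followed. The falls were led by Fbp2 (-2.14 ± 0.44), Zfp970 (-1.90 ± 0.51), Anxa2 (-1.78 ± 0.37), Vim, the intermediate filament vimentin (-1.68 ± 0.22), the tetraspanin gene Cd53 (-1.63 ± 0.37) and Rasgrp4 (-1.59 ± 0.38). Erythroid and heme genes rose, 31 of 38 with 0 falling and 7 not passing (34 adjusted over the list alone, median 0.92, adjusted p = 3.53e-31). Among them were Gypc (2.27 ± 0.18) and Car2, a carbonic anhydrase (2.07 ± 0.18). Megakaryocyte genes had 8 of 16 higher, 0 lower and 8 not passing (11 adjusted over the list alone, median 0.40, adjusted p = 1.69e-07), with Itgb3 at 1.87. Blood transcription factors had 11 of 24 higher, 2 lower and 11 not passing (13 and 3 adjusted over the list alone, median 0.32, adjusted p = 5.59e-06). Gfi1b was at 1.33 ± 0.15 and Lyl1 at 1.08 ± 0.09. These 3 calls held with an estimated correlation. Myc targets and ribosome biogenesis genes shifted up by a median of 0.24 although 2 of 44 members passed (0 lower, 2 adjusted over the list alone, adjusted p = 1.05e-05). That call was lost at adjusted p = 0.644 with an estimated correlation.

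At 2 h limma called 1195 genes, 861 higher and 334 lower (edgeR 1208), or 3945 (2162 higher, 1783 lower) without the doubted libraries. Leaving out degrader 2 h replicate 1 or 2 gave 547 or 556. Sites of the dREG tables changed as well. A site on chromosome 2 (mm39, 127926031 to 127926610) was 3.67 ± 0.31 higher at 15 min (223.5 ± 74.1 against 16.1 ± 1.56, SD, n = 3 each, limma adjusted p = 4.37e-09). It was 4.32 ± 0.34 higher at 2 h (340.7 ± 12.5, SD, n = 2, adjusted p = 2.67e-09). A site on chromosome 15 (78189001 to 78189790) was 3.28 ± 0.15 higher at 15 min, and a site on chromosome 4 (114952561 to 114952870) was 3.35 ± 0.33 higher at 2 h. Sites on chromosome 1 (153285751 to 153286180, -1.35 ± 0.34) and chromosome 3 (85480171 to 85480580, -1.17 ± 0.28) fell most at 15 min. At 2 h the largest falls were at sites on chromosome 16 (39704531 to 39705000, -2.45 ± 0.31) and chromosome 4 (46576611 to 46576960, -2.36 ± 0.34). Of 23307 sites, 3237 were called at 15 min (2734 higher, 503 lower) and 2446 at 2 h (2078 higher, 368 lower), against 5620 (3542 higher, 2078 lower) and 4056 (2952 higher, 1104 lower) without the doubted libraries. The 2 h count was 1431 or 1378 without degrader 2 h replicate 1 or 2.

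**Figure D3:**
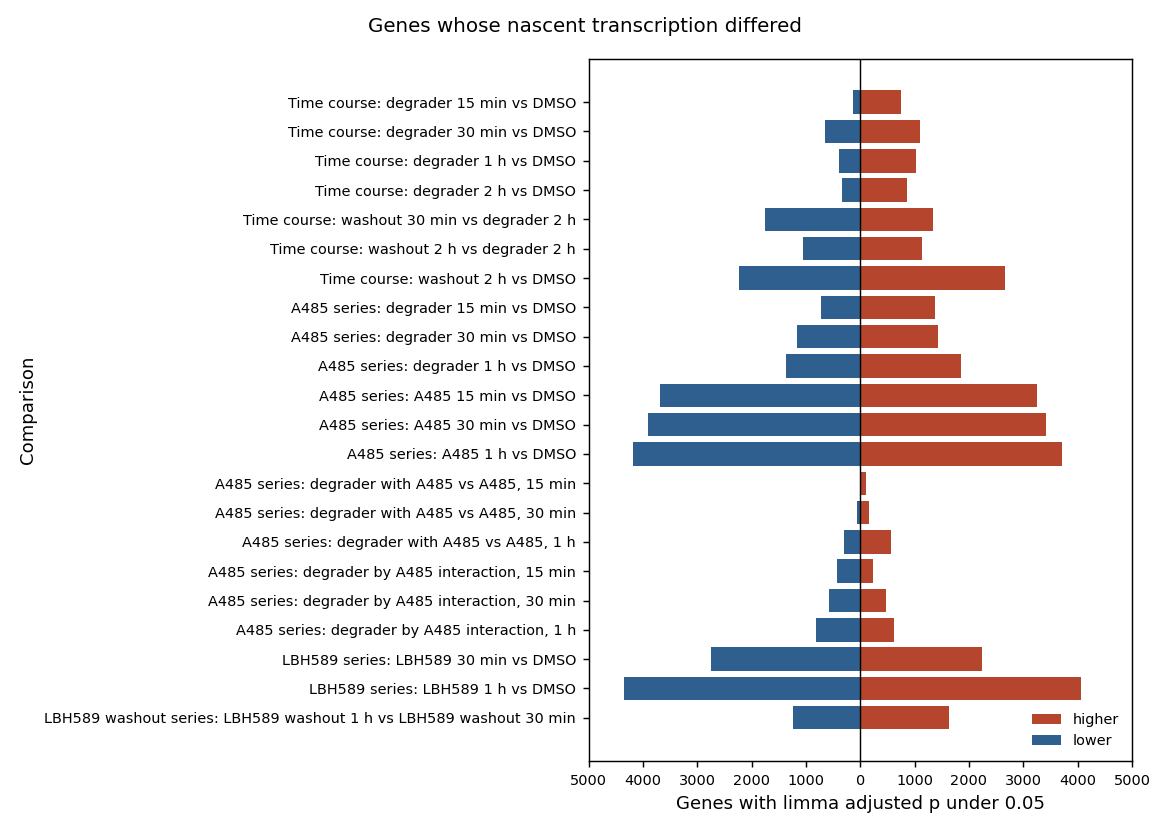
Genes called by limma (adjusted p under 0.05) in each of the 22 gene comparisons, with genes higher in the first group to the right of 0 and genes lower to the left. The counts run from 108 higher and 3 lower (degrader with A485 against A485 at 15 min) to 4064 higher and 4348 lower (LBH589 at 1 h against DMSO).

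Washout asked whether repression returned once the degrader was removed. No group was washed without prior degrader, and no protein was measured. In all washout comparisons of the time course, washing and the change of medium therefore cannot be told apart from a return of Mtg16. After 2 h of washout, Cbfa2t3 stood at -0.62 ± 0.35 against 2 h of degrader, which did not pass (limma adjusted p = 0.241, n = 2 each), and 2.23 ± 0.32 above DMSO (adjusted p = 0.000115). Both washout values (109100 and 111000) lay below both degrader 2 h values (175800 and 163200). The SE draws on the spread of all groups in the fit, including degrader 15 min, which held 58870, 150600 and 48880. The cytokine receptor gene Il31ra rose most against degrader 2 h (2.48 ± 0.54, 2862 ± 169 against 520.3 ± 130, SD, n = 2 each). Next came Dynll1, a dynein light chain (2.01 ± 0.19), Gstm5 (1.96 ± 0.45), the receptor kinase gene Mst1r (1.93 ± 0.30), Ppcs (1.91 ± 0.25) and Uqcr11, a subunit of respiratory complex III (1.87 ± 0.27). Lrrc4c (-2.38 ± 0.56) and Tspoap1 (-2.37 ± 0.26, 975 ± 36.2 against 5036 ± 144, SD, n = 2 each) fell most. Htra4 (-2.04 ± 0.33), Plch1 (-1.63 ± 0.24), Jund, a member of the AP-1 family (-1.62 ± 0.29), and Coro6 (-1.62 ± 0.31) followed. Genes that had risen with 1 h of degrader in the A485 series moved down: of 1845 measured, 397 fell and 73 rose (median -0.17, camera p = 6.46e-10, and p = 0.00263 with an estimated correlation). Against DMSO these genes had a median of 0.12 (632 higher, 297 lower, camera p = 0.0022, and p = 0.082 with an estimated correlation). Across all genes, the change from degrader 2 h to washout correlated with gene length at rho = -0.43, against 0.12 for degrader 1 h in the A485 series. How far the fall of these genes follows their length was not tested.

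Erythroid and heme genes did not move as a group during washout: of 38 measured, 5 rose, 7 fell and 26 did not pass (7 and 8 adjusted over the list alone, median 0.11, adjusted p = 0.983). Hemgn fell by 0.71 ± 0.18, while Ppox, an enzyme of heme synthesis, rose by 0.98. Granulocyte and macrophage genes fell, 6 of 21 with 0 rising (6 adjusted over the list alone, median -0.44, adjusted p = 0.00516), led by Cebpb, a myeloid transcription factor (-1.49 ± 0.24), and Fcgr1, a receptor for immunoglobulin (-1.23 ± 0.15). Their call was lost at adjusted p = 0.382 with an estimated correlation. Lymphoid genes had 3 of 10 lower and 0 higher (3 adjusted over the list alone, median -0.62, adjusted p = 0.0148, and adjusted p = 0.382 with an estimated correlation), with the kinase gene Lck at -0.84 ± 0.19. TGF-beta and Wnt feedback genes had 3 of 11 lower and 0 higher (3 adjusted over the list alone, median -0.23, adjusted p = 0.0246, and adjusted p = 0.382 with an estimated correlation), with Lef1 at -0.79. Heat shock genes had 6 of 16 higher and 0 lower (9 adjusted over the list alone, median 0.35, adjusted p = 0.0148, and adjusted p = 0.382 with an estimated correlation), with the cochaperone gene Ahsa1 at 0.92 ± 0.17. Myc targets and ribosome biogenesis genes had 5 of 44 higher and 0 lower (3 adjusted over the list alone, median 0.21, adjusted p = 0.0148, and adjusted p = 0.701 with an estimated correlation). Cdk4 rose by 0.92 ± 0.20 and Myc itself rose by 1.24 ± 0.26.

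limma called 2198 genes between 2 h of washout and 2 h of degrader, 1142 higher and 1056 lower (edgeR 2411), and 4897 between 2 h of washout and DMSO, 2667 higher and 2230 lower. Without the doubted libraries these counts were 5466 (2821 higher, 2645 lower) and 7524 (4107 higher, 3417 lower). Leaving out degrader 2 h replicate 1 or 2 or either 2 h washout column gave 788, 705, 734 and 618 for the first, and the washout columns gave 2843 and 2554 for the second. Risers were short genes: their median length was 6.54 kb, against 50.1 kb for genes that fell and 21.4 kb for all tested genes. Among dREG sites, 2744 of 23307 were called (1315 higher, 1429 lower), or 5510 (2768 higher, 2742 lower) without the doubted libraries. Sites on chromosome 17 (12731441 to 12732080, 3.20 ± 0.54) and chromosome 12 (16182591 to 16182920, 3.04 ± 0.55) rose most. Sites on chromosome 11 (40646781 to 40647370, -2.33 ± 0.44) and chromosome X (105231561 to 105232110, -2.24 ± 0.37, 404.7 ± 88.6, SD, n = 3, against 1885 ± 57.8, SD, n = 2) fell most. Leaving out degrader 2 h replicate 1 or 2 gave 726 or 727 sites, and 2 h washout replicate 2 or 3 gave 1617 or 1656.

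At 30 min of washout, Eda2r, a member of the TNF receptor family and a known p53 target, was 5.89 ± 1.20 higher than at 2 h of degrader (814.1 ± 105 against 12.9 ± 3.53, SD, n = 2 each). Trp53inp1, another p53 target, was 3.83 ± 0.81 higher and Islr2 2.24 ± 0.51. The acid phosphatase gene Acp5 fell by 1.96 ± 0.41, Ccnb1ip1 by 1.93 ± 0.47 and the progenitor transcription factor Myb by 1.84 ± 0.41, while Cbfa2t3 was at -0.07 ± 0.35 (adjusted p = 0.899). limma called 3091 genes, 1336 higher and 1755 lower (edgeR 3313), and 6480 (3137 higher, 3343 lower) without the doubted libraries. When degrader 2 h replicate 1, degrader 2 h replicate 2, 30 min washout replicate 1 or 30 min washout replicate 2 was left out, limma called 0 genes each time, with 3391, 3778, 3543 and 3871 at an unadjusted p under 0.05, and edgeR called 0.

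The A485 series repeated the degrader times with new libraries. At 1 h, Slc22a4 rose most (2.89 ± 0.15, 1171 ± 45.3 against 157.6 ± 9.91, SD, n = 3 each, limma adjusted p = 8.55e-17). Next came Cdkl1, a kinase gene (2.25 ± 0.19), Cdc42ep1 (2.19 ± 0.26), Cbfa2t3 (2.18 ± 0.11), Frmd4a (2.04 ± 0.07) and Ak8 (2.04 ± 0.09). The histone H2B genes H2bc22 (-2.39 ± 0.23), H2bc4 (-1.96 ± 0.13, 374.4 ± 78.6 against 1437 ± 29.7, SD, n = 3 each) and H2bc21 (-1.90 ± 0.17) fell most. They were followed by Ftl1, the ferritin light chain (-1.64 ± 0.15), Ier3, an immediate early gene (-1.60 ± 0.30), and Zfp970 (-1.45 ± 0.27). limma called 3220 of 12597 genes, 1850 higher and 1370 lower (edgeR 3541). At 15 min it called 2098, 1368 higher and 730 lower, led by Ltf, which encodes lactoferrin (1.45 ± 0.25), and by a fall in Slc6a2 (-1.66 ± 0.23). At 30 min it called 2592, 1429 higher and 1163 lower, led by Slc22a4 (1.75 ± 0.15) and Slc6a2 (-1.56 ± 0.23). The 15 min count was 1398 without DMSO replicate 4.

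Erythroid and heme genes rose again, 27 of 37 with 0 falling and 10 not passing at 1 h (27 adjusted over the list alone, median 0.50, adjusted p = 1.47e-18). They included Gypc (1.67 ± 0.08), the mitochondrial transporter gene Abcb10 (1.11 ± 0.06) and Sptb, the spectrin beta chain (0.83). Blood transcription factors had 14 of 25 higher, 2 lower and 9 not passing (14 and 6 adjusted over the list alone, median 0.33, adjusted p = 0.000635), with Myb at 1.20 ± 0.05 and Gfi1b at 1.19 ± 0.08. Immediate early genes, which respond within minutes to stimuli, fell, 15 of 34 with 3 rising and 16 not passing (16 and 4 adjusted over the list alone, median -0.25, adjusted p = 0.000635). Egr1 was at -0.82 ± 0.05. These 3 calls held with an estimated correlation. Megakaryocyte genes had 7 of 15 higher and 0 lower (7 adjusted over the list alone, median 0.23, adjusted p = 0.0127), lost at adjusted p = 0.101 with an estimated correlation. Unfolded protein and amino acid stress genes had 8 of 21 lower and 1 higher (10 and 1 adjusted over the list alone, median -0.16, adjusted p = 0.00332, and adjusted p = 0.0722 with an estimated correlation). Chac1 was at -0.89 and the chaperone gene Hspa5 at -0.56. Heat shock genes had 8 of 16 lower and 1 higher (9 and 1 adjusted over the list alone, median -0.11, adjusted p = 0.00472, and adjusted p = 0.0577 with an estimated correlation). Myc targets had 12 of 44 lower and 1 higher (13 and 1 adjusted over the list alone, median -0.10, adjusted p = 0.011, and adjusted p = 0.347 with an estimated correlation).

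The genes called in the time course and in the A485 series overlapped. At 15 min 397 genes were higher in both, where independent lists would share 79, and 26 were lower in both against 7.7. At 30 min the overlaps were 533 against 122 and 146 against 61.2, and at 1 h 735 against 147 and 193 against 43.9. Across genes, fold changes correlated at r = 0.49, 0.35 and 0.64 (Spearman rho 0.33, 0.15 and 0.45), and 17, 85 and 10 genes were called in opposite directions. Among the genes called in the same direction after 30 min in the time course and after 1 h in the A485 series, the 10 whose larger p was smallest all rose. They were Micall2 (1.63 ± 0.07 and 1.53 ± 0.13), Tnfaip8 (0.93 ± 0.05 and 0.58 ± 0.04), Gfod1 (1.69 ± 0.10 and 1.33 ± 0.06), Prkar2b, a regulatory subunit of protein kinase A (1.21 ± 0.07 and 1.08 ± 0.05) and the thrombin receptor gene F2r (1.88 ± 0.09 and 0.67 ± 0.07). The next were Celf4 (1.03 ± 0.06 and 0.92 ± 0.08), Uba7 (1.90 ± 0.10 and 1.30 ± 0.13), Cd47 (0.99 ± 0.07 and 0.51 ± 0.05), Hemgn (2.24 ± 0.14 and 1.59 ± 0.17) and Ptpre (1.15 ± 0.06 and 0.35 ± 0.04). Genes higher at 1 h in the A485 series had a median of 0.24 at 2 h of degrader in the time course (649 higher, 2 lower of 1845, camera p = 8.81e-06 with an estimated correlation).

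At dREG sites in the A485 series, a site on chromosome 5 (24127301 to 24129170) rose by 2.39 ± 0.14 at 15 min (822.6 ± 6.21 against 157.7 ± 28.1, SD, n = 3 each, adjusted p = 2.1e-14) and by 2.98 ± 0.14 at 1 h (1236 ± 63.4, SD, n = 3). A site on chromosome 7 (79792651 to 79794320) rose by 2.21 ± 0.22 and 2.85 ± 0.22. At 15 min a pair of sites on chromosome 1 fell most (21413821 to 21415010, -1.45 ± 0.27, and 23865841 to 23867350, -1.41 ± 0.15). At 1 h a pair of sites on chromosome 13 fell most, the first (23741061 to 23741380) at -3.66 ± 0.18, from 897.3 ± 68.3 to 70.7 ± 13.7 (SD, n = 3 each), and the second (23743981 to 23744890) at -3.49 ± 0.23. Of 21312 sites, 1159 were called at 15 min (897 higher, 262 lower) and 5668 at 1 h (3457 higher, 2211 lower). With TMM scaling the 15 min split was 763 higher and 370 lower, and edgeR called 1837 sites there. The 15 min count was 506, 559 and 618 without DMSO replicate 4 and degrader 15 min replicates 4 and 5, and the 1 h count was 3777 without DMSO replicate 4.

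A485 inhibits the acetyltransferases p300 and CBP. After 1 h Gp1ba, the platelet glycoprotein Ib alpha chain, fell most, to a log2 change of -6.12 ± 0.38 (0.957 ± 1.66 against 108.3 ± 6.93 normalised reads, SD, n = 3 each, limma adjusted p = 6.59e-16). Inka1 (-4.88 ± 0.46), Micall2 (-4.69 ± 0.13), Treml2 (-4.57 ± 0.09), Alas2 (-4.55 ± 0.17) and the inflammasome gene Nlrp6 (-4.26 ± 0.28) followed. The largest rises were smaller, in Klhl32 (1.87 ± 0.37), Lrrc75b (1.86 ± 0.22), Myh14, a nonmuscle myosin (1.71 ± 0.19), Prrt1 (1.68 ± 0.22), Nxf2 (1.62 ± 0.20) and Tmem169 (1.61 ± 0.17). limma called 7889 genes, 3703 higher and 4186 lower, of which 258 and 1222 by at least 1 on the log2 scale. At 15 min it called 6941 (3249 higher, 3692 lower), with Gp1ba at -4.23 ± 0.38 and the water channel gene Aqp1 at -3.73 ± 0.09. At 30 min it called 7323 (3419 higher, 3904 lower, n = 2 against 3), with Il1rl1, the interleukin-33 receptor, at -4.31 ± 0.28. The A485 libraries at 30 min and 1 h carry replicate numbers from 1 to 3, while DMSO and A485 at 15 min carry 4 to 6. A shift shared by a set of numbers could not be told apart from A485 at these 2 times.

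With 1 h of A485, 10 gene lists fell and none rose. Erythroid and heme genes had 35 of 37 lower and 1 higher (35 and 1 adjusted over the list alone, median -1.60, adjusted p = 8.21e-16), including Aqp1 (-3.94 ± 0.09) and Alas2 (-4.55 ± 0.17). Blood transcription factors had 21 of 25 lower and 1 higher (21 and 1 adjusted over the list alone, median -1.40, adjusted p = 1.42e-10). Zfpm1, the GATA1 cofactor FOG1, was at -3.77 ± 0.06, Ikzf1 at -2.41 ± 0.04 and Myb at -2.37 ± 0.05. Immediate early genes had 31 of 34 lower and 1 higher (32 and 1 adjusted over the list alone, median -1.12, adjusted p = 1.23e-07), with Klf10 at -2.31. JAK-STAT feedback and cytokine signalling genes had 21 of 26 lower and 2 higher (21 and 2 adjusted over the list alone, median -0.84, adjusted p = 2.32e-07), with the cytokine receptor gene Csf2rb at -3.55 ± 0.08 and Stat3 at -1.73. Megakaryocyte genes had 12 of 15 lower and 0 higher (12 adjusted over the list alone, median -1.68, adjusted p = 5.31e-06), with Itga2b, integrin alpha IIb, at -2.60 ± 0.07 and Fli1 at -1.68 ± 0.03. Stem and progenitor genes had 8 of 15 lower and 2 higher (8 and 2 adjusted over the list alone, median -0.78, adjusted p = 0.00676), with Meis1 at -1.97 ± 0.04. These 6 calls held with an estimated correlation.

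The other lists that fell with A485 lost their call. Granulocyte and macrophage genes had 10 of 18 lower and 1 higher (10 and 1 adjusted over the list alone, median -0.49, adjusted p = 0.0253, and adjusted p = 0.183 with an estimated correlation), with the myeloid regulator Spi1 at -2.42. NF-kB and interferon genes had 15 of 24 lower and 4 higher (15 and 4 adjusted over the list alone, median -0.51, adjusted p = 0.0253, and adjusted p = 0.137 with an estimated correlation). Unfolded protein and amino acid stress genes had 13 of 21 lower and 0 higher (13 adjusted over the list alone, median -0.51, adjusted p = 0.00296, and adjusted p = 0.0587 with an estimated correlation), with Ddit3 at -1.95. Heat shock genes had 9 of 16 lower and 0 higher (9 adjusted over the list alone, median -0.31, adjusted p = 0.0253, and adjusted p = 0.099 with an estimated correlation). Among dREG sites, 9138 were called (4027 higher, 5111 lower). A site on chromosome 8 (123030141 to 123030570) fell most, at -5.4 ± 0.41 (4.54 ± 4.26 against 163.9 ± 22.2, SD, n = 3 each), with one on chromosome 15 (67023321 to 67024300) at -5.09 ± 0.40. Sites on chromosome 3 (96846221 to 96847040, 3.34 ± 0.24) and chromosome 7 (3597561 to 3598280, 2.32 ± 0.24) rose most.

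Adding degrader to A485 asked whether genes respond to Mtg16 loss while p300 and CBP are inhibited. At 1 h, Cbfa2t3 was 2.81 ± 0.11 higher with both agents than with A485 alone, Gfi1b 2.21 ± 0.08 (1537 ± 24.7 against 335.2 ± 66.7, SD, n = 3 each) and Gypc 2.01 ± 0.08. Efcab6 (-2.98 ± 0.70), Klhl32 (-2.27 ± 0.37) and Cnih3 (-1.86 ± 0.37) were lower. At 15 min Hemgn (1.27 ± 0.17), Gadd45a, a stress response gene (1.04 ± 0.14), and Gfi1b (1.00 ± 0.08) were higher and the 3 lower genes were Evi2 (-0.46 ± 0.08), Evi2b (-0.31 ± 0.07) and Egr1 (-0.28 ± 0.05). At 30 min Hemgn (1.68 ± 0.21), Gypc (1.33 ± 0.10) and Gfi1b (1.32 ± 0.10) were higher and Acsl6 (-1.08 ± 0.21), Vim (-0.91 ± 0.18) and Camkv (-0.87 ± 0.23) lower. limma called 111 genes at 15 min (108 higher, 3 lower, edgeR 140), 228 at 30 min (165 higher, 63 lower, edgeR 109, n = 2 each) and 869 at 1 h (574 higher, 295 lower, edgeR 578). Leaving out 1 library gave 71 at 15 min (both agents replicate 5), 115 and 133 (A485 replicates 1 and 2) or 446 and 116 (both agents replicates 1 and 2) at 30 min, and 565 and 523 (both agents replicates 1 and 2) at 1 h.

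The interaction tested how far the degrader's effect differed with A485. Gfi1b had a larger effect with A485 at 1 h (1.03 ± 0.12, adjusted p = 2.34e-07), as did Cbfa2t3 (0.63 ± 0.15, adjusted p = 0.00572). The interaction of Cbfa2t3 did not pass at 15 min (-0.34 ± 0.15, adjusted p = 0.23) or 30 min (-0.47 ± 0.17, adjusted p = 0.0865). Effects smaller with A485 included Slc22a4 (-1.83 ± 0.21), which went from 157.6 ± 9.91 in DMSO to 1171 ± 45.3 with degrader but from 46.3 ± 12.6 with A485 to 95.2 ± 11.9 with both (SD, n = 3 each). Others were Scn10a (-2.10 ± 0.30), Asb17 (-1.87 ± 0.22) and Erg, a transcription factor of stem cells and megakaryocytes (-1.18 ± 0.19). Klhl32 (-2.15 ± 0.53), Lrrc75b (-1.94 ± 0.31) and Bcan (-1.73 ± 0.32) also had negative interactions. The largest positive interactions were in H2bc22 (2.41 ± 0.32), H2bc4 (2.17 ± 0.19), the metallothionein gene Mt1 (1.97 ± 0.32), Inka1 (1.95 ± 0.65), Gp1ba (1.85 ± 0.53) and H2bc21 (1.75 ± 0.23). For the histone genes this came from a DMSO level above all 9 treated groups: H2bc4 was 1437 ± 29.7 in DMSO, 374.4 ± 78.6 with degrader, 491.8 ± 45.1 with A485 and 568.9 ± 27.9 with both at 1 h (SD, n = 3 each).

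limma called 670 interactions at 15 min (241 positive, 429 negative), 1033 at 30 min (465 and 568) and 1453 at 1 h (629 and 824). Leaving out 1 library gave 414 and 435 at 15 min (DMSO replicate 4, degrader replicate 4), and 635, 666, 613 and 498 at 30 min (DMSO replicate 4, A485 replicates 1 and 2, both agents replicate 2). Of 37 erythroid and heme genes, 11 had a smaller effect with A485 at 1 h, 2 a larger one and 24 did not pass (13 and 2 adjusted over the list alone, median -0.23, adjusted p = 1.06e-05), Abcb10 at -0.71 ± 0.09 and Sptb at -0.61 ± 0.07. Immediate early genes went the other way, with 11 of 34 positive and 1 negative (11 and 1 adjusted over the list alone, median 0.40, adjusted p = 0.00011), Egr1 at 0.69 ± 0.07 and Zfp36, a regulator of mRNA decay, at 1.51 ± 0.27. Both calls held with an estimated correlation. The other called lists lost their call. Unfolded protein and amino acid stress genes had 5 of 21 positive and 1 negative (8 and 1 adjusted over the list alone, median 0.21, adjusted p = 0.000883, and adjusted p = 0.0609 with an estimated correlation). Heat shock genes had 3 of 16 positive and 0 negative (5 adjusted over the list alone, median 0.11, adjusted p = 0.011, and adjusted p = 0.0808 with an estimated correlation). Stem and progenitor genes had 5 of 15 negative and 1 positive (6 and 1 adjusted over the list alone, median -0.20, adjusted p = 0.0281, and adjusted p = 0.1 with an estimated correlation). Myc targets had 4 of 44 positive and 1 negative (6 and 1 adjusted over the list alone, median 0.09, adjusted p = 0.0128, and adjusted p = 0.396 with an estimated correlation). The same DMSO libraries enter degrader against DMSO with the opposite sign. The directions of these interactions are therefore not independent of the degrader changes given above.

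Among dREG sites, 3465 interactions were called (1392 positive, 2073 negative), or 2159 without DMSO replicate 4. The chromosome 13 sites that fell with degrader had the largest positive ones (23741061 to 23741380, 3.86 ± 0.25, and 23743981 to 23744890, 3.39 ± 0.33). Sites on chromosome 14 (50703591 to 50704090, -2.75 ± 0.60) and chromosome 1 (132334231 to 132334940, -2.38 ± 0.35) had the largest negative ones. The positive interactions on chromosome 13 came from a DMSO level above the treated groups. The first site was at 897.3 ± 68.3 in DMSO, 70.7 ± 13.7 with degrader, 86.7 ± 10 with A485 and 99 ± 3.53 with both (SD, n = 3 each). The second was at 295.7 ± 70.8, 25.3 ± 5.9, 40.9 ± 12 and 37.3 ± 5.19 in the same order.

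LBH589 inhibits histone deacetylases. After 1 h, Efna3, an ephrin ligand, rose by 2.37 ± 0.17 (193.1 ± 18.6 against 37.7 ± 12.7, SD, n = 3 each, limma adjusted p = 7.02e-13). Ptgr1 (2.00 ± 0.13), the receptor kinase gene Ltk (1.99 ± 0.16), the leukotriene receptor gene Cysltr1 (1.95 ± 0.16), Insl6 (1.87 ± 0.18) and Cnnm1 (1.87 ± 0.16) followed. Col5a1, a collagen chain (-1.82 ± 0.05), Pilrb2 (-1.74 ± 0.13) and Myb (-1.61 ± 0.04, 3140 ± 134 against 9568 ± 205, SD, n = 3 each) fell most. Epb42 (-1.5 ± 0.14), Zfpm1 (-1.43 ± 0.04) and Myc (-1.36 ± 0.05) followed. limma called 8412 of 12553 genes, 4064 higher and 4348 lower, of which 252 and 110 by at least 1 on the log2 scale, and 4978 at 30 min (2232 higher, 2746 lower). With TMM scaling the larger side turned, to 4324 higher and 4096 lower at 1 h and 2487 higher and 2458 lower at 30 min. At 30 min Slc6a2 (1.59 ± 0.16), Islr2 (1.53 ± 0.13) and Npnt (1.33 ± 0.14) rose most, and Myb (-1.40 ± 0.04), Myc (-1.36 ± 0.05) and Zfpm1 (-1.26 ± 0.04) fell most.

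At 1 h of LBH589, 42 of 44 Myc targets and ribosome biogenesis genes fell and 0 rose (42 adjusted over the list alone, median -0.51, adjusted p = 3.67e-12, and adjusted p = 0.172 with an estimated correlation). They included Srm, spermidine synthase (-1.16 ± 0.05), and Eif5a, a translation factor (-0.96 ± 0.04). Blood transcription factors had 18 of 24 lower and 2 higher (18 and 2 adjusted over the list alone, median -0.46, adjusted p = 3.17e-05, and adjusted p = 0.172 with an estimated correlation), with Gfi1b at -1.04 and Lyl1 at -1.03. Cell cycle genes had 28 of 39 lower and 7 higher (28 and 7 adjusted over the list alone, median -0.20, adjusted p = 0.00594, and adjusted p = 0.37 with an estimated correlation), with Cdk6 at -0.67 ± 0.03. Erythroid and heme genes had 23 of 37 lower and 6 higher (24 and 6 adjusted over the list alone, median -0.26, adjusted p = 0.00729, and adjusted p = 0.241 with an estimated correlation), with Gypc at -0.72 ± 0.04. Of 22740 dREG sites, 8273 were called (3952 higher, 4321 lower, and 4217 and 3991 with TMM scaling). Sites on chromosome 1 (64778211 to 64778780, 2.18 ± 0.13) and chromosome 2 (132421801 to 132422780, 1.96 ± 0.15) rose most, and sites on chromosome 15 (37071961 to 37072160, -2.36 ± 0.21) and chromosome 2 (27957051 to 27957930, -2.24 ± 0.24) fell most.

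The LBH589 washout series compared 1 h with 30 min of washout after 2 h of degrader, in cells that also received LBH589. Its labels do not say how LBH589 was timed against the degrader. Tubg1, a gamma tubulin, was 1.83 ± 0.28 higher at 1 h (119.1 ± 50.1 against 31 ± 2.56, SD, n = 3 each, limma adjusted p = 0.00343), Mical1 1.78 ± 0.20 and Arl16 1.72 ± 0.27. The histone genes H2bc22 (-2.26 ± 0.31) and H2bc4 (-2.23 ± 0.23, 100.9 ± 30.6 against 472.4 ± 103, SD, n = 3 each) and Myb (-1.98 ± 0.21) fell most. limma called 2879 of 12342 genes, 1634 higher and 1245 lower. Leaving out 1 library gave 1583, 859 and 943 (30 min washout replicates 1, 2 and 3) and 4492 (1 h washout replicate 3). Of 17435 dREG sites, 965 were called (494 higher, 471 lower, and 463 and 511 with TMM scaling). Sites on chromosome 11 (77985501 to 77986100, 2.61 ± 0.36) and chromosome 3 (153556611 to 153557060, 2.2 ± 0.44) rose most, and a pair of sites on chromosome 13 (21968761 to 21970220, -2.85 ± 0.28, and 23741061 to 23741380, -2.73 ± 0.26) fell most. Leaving out the same 4 libraries gave 70, 5, 4 and 2409 sites.

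The 1106 genes that rose after 30 min of degrader in the time course were followed as a group in the other experiments, of which the time-course libraries are no part. Of the 1073 measured in the A485 series, 706 rose and 23 fell with 1 h of degrader (median 0.39, quartiles 0.14 and 0.76, camera p = 1.16e-08 with an estimated correlation), with medians of 0.20 at 15 min and 0.25 at 30 min. With A485 alone 784 fell and 76 rose at 1 h (median -0.75, quartiles -1.51 and -0.21, p = 1.6e-06 with an estimated correlation), and the medians were -0.50 and -0.60 at 15 and 30 min. When degrader was added to A485, 316 rose and 13 fell at 1 h (median 0.14, p = 1.47e-06 with an estimated correlation), 92 rose and 0 fell at 15 min (median 0.08) and 106 rose and 4 fell at 30 min (median 0.07). The interaction at 1 h was negative for 310 and positive for 42 of them (median -0.17, p = 4.51e-05 with an estimated correlation). With 30 min of LBH589, 352 of 1084 fell and 193 rose (median -0.04, p = 0.0613, and p = 0.0214 with an estimated correlation). With 1 h of LBH589, 462 of 1084 fell and 281 rose (median -0.07, p = 0.0213, and p = 0.00893 with an estimated correlation), and between the LBH589 washout times the median was 0.02 (p = 0.491).

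**Figure D4:**
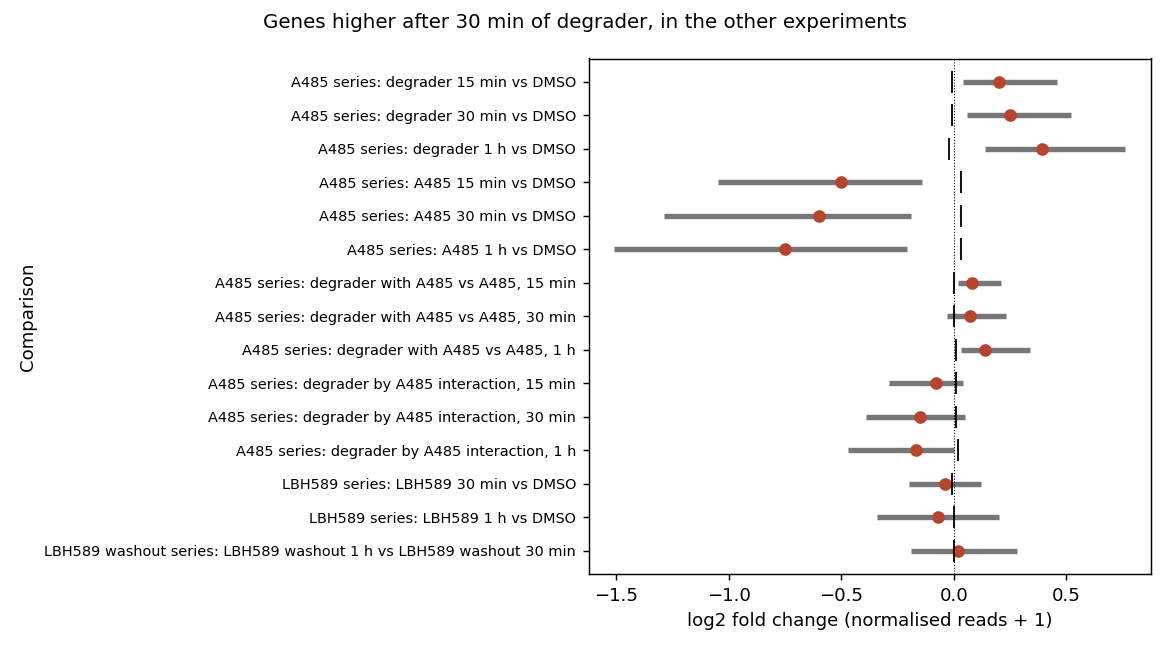
Log2 fold change (x axis) of the genes called higher after 30 min of degrader in the time course, in the comparisons of the other experiments (y axis). Red points are medians, grey bars run from the lower to the upper quartile and black ticks are the medians of all other genes; the medians run from -0.75 with A485 for 1 h to 0.39 with degrader for 1 h.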

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

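The tests of exchanged labels and of depth for the 3 time-course libraries, and the sorting of the interaction splits by balance and their redrawing within the libraries with and without A485, were chosen only after those results were seen.

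Differences between the degrader's effects with and without A485, each from the interaction term, marked 670 genes at 15 min, 1033 at 30 min and 1453 at 1 h, and 3465 dREG sites at 1 h. Signal above the control level was also seen in a pair of time-course gene columns that no comparison used: Cbfa2t3 stood at 136900 in the column named 30 min washout replicate 3 and at 111000 in the column named 1 h washout replicate 2, against 23810 ± 4797 in DMSO (SD, n = 3).

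In the time course, degrader 30 min replicate 3 and 30 min washout replicate 3 stood apart from their groups at dREG sites (mean r of -0.25 and -0.23). Depth is argued against for degrader 30 min replicate 3, which held 5146151 reads, inside the range of the other libraries (1969884 to 6959404, the upper end being degrader 15 min replicate 2, with 6865722 the next below). An exchange of these labels would need each library to correlate with the other group, and it did, at 0.72 and at 0.52, so exchanged labels are a candidate explanation that stays open. For degrader 15 min replicate 2, whether a wrong label or something else set it apart cannot be told apart: its highest mean r with another group was 0.46 (1 h washout, gene table, 0.23 at dREG sites), which lies between own-group values of the other libraries, while the 1 h washout libraries did not match 15 min replicates 1 and 3 (r = -0.46 and -0.44 for genes, -0.42 to -0.38 at sites), which speaks against an exchange between these 2 groups. No biological explanation was tested.

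Fewer genes passed for degrader on top of A485 than for degrader alone at 1 h (869 against 3220), and the interaction of the genes that rise with degrader was negative. Lower depth of the A485 libraries (7453718 to 14686743 reads, against 21400590 to 27309451 in DMSO) is argued against: with DMSO thinned to those depths and degrader to those of the libraries with both agents (20053461 to 28569036), degrader alone still gave 3250 to 3314 genes. Rises hidden because genes lie near 0 under A485 are argued against as well, since the median interaction was -0.15 in the 887 listed genes with a mean of at least 50, of which 281 were negative and 35 positive. A smaller response while p300 and CBP are inhibited stays open as a hypothesis found and tested on the same data.

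The largest rises after 2 h of washout were in short genes (median 3.9 kb, against 21.4 kb for tested genes). A trend on gene length may account for part of this, since length and fold change correlated at rho = -0.43 across all genes, against -0.05 at 30 min of washout. With each library's trend on length removed, 1470 genes passed (641 higher, 829 lower), against 2198 before (1142 higher, 1056 lower) and a bound of 1465 set for the test, and 1092 were called both times in the same direction. Whether the trend or the washout itself made the calls cannot be told apart, because the count ended so near the bound. The 6 named risers were still called.

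The same libraries were also split in other ways into groups of the same size. With a pair of groups, every other split mixes their libraries, so a real difference adds to the spread and shrinks the contrast. The low counts and medians of those splits therefore do not show what chance alone would give. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each count of this kind 1 split, the real one, gave a result as large. For genes, the real count and the highest other were 881 and 299 at 15 min, 1764 and 2 at 30 min and 1435 and 0 at 1 h of degrader in the time course. In the A485 series they were 2098 and 0, 2592 and 0, and 3220 and 0 for degrader at the same times, 6941 and 0 for A485 at 15 min and 7889 and 1 at 1 h, and 111 and 0 at 15 min and 869 and 10 at 1 h for degrader on top of A485. For LBH589 they were 4978 and 0 at 30 min and 8412 and 0 at 1 h, and for the LBH589 washout 2879 and 0. At dREG sites they were 3237 and 4 (degrader 15 min, time course), 1159 and 0 (degrader 15 min, A485 series), 5668 and 0 (degrader 1 h), 9138 and 150 (A485 1 h), 8273 and 0 (LBH589 1 h) and 965 and 0 (LBH589 washout).

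For the genes that rose after 30 min of degrader in the time course, the size of the median and the highest other were 0.39 and 0.15 with degrader 1 h, 0.75 and 0.29 with A485 1 h, 0.14 and 0.08 with degrader on top of A485, and 0.07 and 0.04 with LBH589, again 1 of 10 splits each. For the LBH589 washout 9 of 10 splits gave a median as large (0.02, highest other 0.08).

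The interactions had more splits, of which 100 were drawn. As many genes came from 6 of 100 at 15 min (670, highest other 5119) and from 5 of 100 at 1 h (1453, highest other 6158). These shares do not fall under 0.05, but they cannot decide on chance. Splits that divide the A485 libraries unevenly carry the effect of A485 itself. At dREG sites 4 of 100 gave as many (3465, highest other 5540), a share under 0.05 with the same limit. A median as large for the list of degrader genes came from 60 of 100 (0.17, highest other 1.45). That share cannot decide on chance either, since the list had a median of -0.75 with A485 alone and its splits were not sorted by balance. The other splits with as many calls (5, 4 and 3) all divided the A485 libraries unevenly, and among the 46 that divided them evenly the highest counts were 0, 131 and 772. When the degrader label was instead redrawn within the libraries with and without A485, 10, 7 and 3 of 100 splits gave as many calls (genes at 15 min and 1 h, sites at 1 h), the real one included, with highest others of 1190, 2070 and 4453. A redraw that keeps the real degrader labels on a single side of A485 leaves the degrader's own effect in the interaction. These shares therefore do not measure chance alone.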

How the results depend on the processing

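The fits without the 3 doubted time-course libraries and those with every gene column as named were chosen after seeing the data, as tests of those libraries. Of 22 gene counts under 260 alternatives, 216 stayed within 1.5 times, as did 86 of 105 for the 9 site counts. For named genes 7116 of 7566 alternatives kept side and direction, 447 were weaker, 3 stronger and 0 reversed, and for named sites 413 of 420 kept them and 7 were weaker. The lists followed across experiments stayed on the same side of the threshold in all 110, the LBH589 washout on the side without a call. An estimated correlation was not among these alternatives, and it ended the call for 2 h of washout against DMSO (camera p = 0.0022, and p = 0.082 with an estimated correlation). For the 140 tests of fixed lists, 1728 of 1820 alternatives kept call and direction, 29 were weaker, 17 stronger and 46 reversed, the last all in lists called in neither fit. The pseudocount and TMM moved no count by over 1.5 times. At the depth and spread of these libraries, simulated changes of 1 were recovered for 61.4% of sites and 92.8% of genes (degrader 1 h, A485 series), and no run separated depth from spread.

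Without the doubted libraries, gene counts in the time course were 3533, 2679, 3842 and 3945 for degrader 15 min, 30 min, 1 h and 2 h, 6480 for 30 min of washout, and 5466 and 7524 for 2 h of washout against degrader and DMSO. Site counts were 5620, 4056 and 5510 for degrader 15 min, 2 h and washout. Of these comparisons, only degrader 15 min and 30 min use any of the doubted libraries. In the others the fold changes were the same, and only the spread shared by the fit changed. Without libraries with conflicting labels the 30 min count was 917. edgeR gave 109 and 578 for degrader on top of A485 at 30 min and 1 h, and 1837 sites for degrader 15 min in the A485 series. The cause of the other differences was not tested.

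Leaving out 1 library at a time, so that a lone sample is taken to vary like the other groups, gave in the time course 587 to 1301 genes at 15 min, 972 to 2443 at 30 min and 547 to 956 at 2 h. For 2 h of washout it gave 618 to 788 against degrader and 2554 to 4169 against DMSO, and for sites 1378 to 2262 at 2 h and 726 to 1835 for washout. For 30 min of washout limma gave 0 each time (3391 to 3871 at an unadjusted p under 0.05), and edgeR 0. In the A485 series the ranges were 1398 to 1699 for degrader 15 min, 71 to 121, 115 to 446 and 523 to 916 for degrader on top of A485 at 15 min, 30 min and 1 h, and 414 to 603 and 498 to 1111 for the interaction at 15 and 30 min. Site ranges were 506 to 1033 at 15 min, 3777 to 4826 at 1 h and 2159 to 4734 for the interaction. The LBH589 washout ranged from 859 to 4492 genes and 4 to 2409 sites.

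The direction of uncalled fixed-list tests reversed in the following fits, given with each list's median. With edgeR, Id, Hes and Notch genes were at 0.01 (degrader 30 min, time course) and 0.04 (degrader 1 h, A485 series) and acetyltransferases at 0.08 (A485 1 h). Without the doubted libraries, at degrader 30 min, cell cycle genes were at -0.04, p53 targets at -0.04, Myc targets at 0 and TGF-beta genes at -0.1, and for washout acetyltransferases were at -0.02 and erythroid genes at 0.11. With columns as named, Id, Hes and Notch genes were at 0 (degrader 30 min), and for washout acetyltransferases at -0.02 and erythroid genes at 0.11. With no filter, Id, Hes and Notch genes were at 0.09 and lymphoid genes at -0.23 (degrader 1 h, A485 series) and 0.28 (interaction). Leaving out 1 library gave, at degrader 30 min in the time course, -0.02 to 0.12 for Id, Hes and Notch, -0.12 to 0.03 for NF-kB, -0.11 to -0.01 for unfolded protein, -0.04 to 0.1 for cell cycle, -0.04 to 0.47 for p53, -0.02 to 0.02 for MTG family, 0 to 0.22 for Myc and -0.1 to 0.02 for TGF-beta genes. At 2 h immediate early genes ranged from -0.18 to -0.05 and unfolded protein genes from -0.12 to 0.03, and for washout erythroid genes from 0.02 to 0.11 and acetyltransferases from -0.05 to -0.02. In the A485 series, degrader 1 h gave 0.01 to 0.09 for Id, Hes and Notch and -0.07 to -0.03 for MTG family genes, A485 1 h gave 0.07 to 0.09 for acetyltransferases and -0.01 to 0.05 for Myc targets, and the interaction gave -0.02 to 0.03 for MTG family and -0.07 to 0.17 for granulocyte genes. The cause was not tested.

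Replicate numbers did not clearly pair the samples. Of pairs with the same number, 10 of 36 in the time course and 4 of 58 in the A485 series correlated over 0.1. In the LBH589 series it was 1 of 3, and in the LBH589 washout series 0 of 3. In the time course the median r was 0.03 for the same number and -0.02 for different numbers. With so few pairs in the LBH589 experiments and outlying libraries in the time course, this check cannot exclude pairing. With the number as a block, no count moved by over 1.5 times (1368 genes for degrader 30 min in the time course, 3137 for degrader 1 h in the A485 series, 2976 for the LBH589 washout), while Id, Hes and Notch genes reversed at degrader 30 min (median 0) and immediate early genes at 2 h (-0.09) in the time course. No paired analysis was possible for A485 at 30 min and 1 h, for LBH589 or for 2 h of washout in the gene table, because the groups share no usable numbers. The gene test of 1 h of washout against degrader was not run, since 1 usable library was left.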

Other observations

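The list tests in these paragraphs, for 30 min of washout, 30 min of LBH589 and the LBH589 washout, and the genes named from them were chosen only after the data were seen.

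After 30 min of washout in the time course, p53 targets rose against 2 h of degrader. Of 21 cyclin-dependent kinase inhibitors and p53 targets, 11 rose, 0 fell and 10 did not pass (14 adjusted over the list alone, median log2 change 0.82, adjusted p = 0.00154, and adjusted p = 0.93 with an estimated correlation, n = 2 each). Without the 3 doubted libraries, 16 rose, 2 fell and 3 did not pass (19 past the threshold adjusted over the list alone, adjusted p = 0.00129, and adjusted p = 0.66 with an estimated correlation). None of those libraries is in this gene comparison, so the median stayed at 0.82. Only the spread shared by the fit changed, and this is no separate check of the rise. Eda2r rose by 5.89 ± 1.20 (SE) and Bbc3, which encodes the apoptosis protein PUMA, by 2.24 ± 0.47 (1132 and 2154 in the 2 washout libraries, against 345.5 and 313.5). These member calls were lost whichever library of the comparison was left out, in fits that leave a lone library in a group. Eda2r and Bbc3 still stood higher in each washout library than in each degrader 2 h library (Eda2r 10.4 and 15.4 in the latter). Immediate early genes had 7 of 32 higher and 1 lower (10 adjusted over the list alone, median 0.32, adjusted p = 0.00834, and adjusted p = 0.93 with an estimated correlation), with Maff at 1.71 ± 0.44 and Atf3, a stress transcription factor, at 1.40 ± 0.34. Without the doubted libraries 13 were higher and 4 lower (17 past the threshold adjusted over the list alone, adjusted p = 0.013, and adjusted p = 0.83 with an estimated correlation), again with the same median of 0.32. Eda2r stood at 739.5 and 888.6 in the 30 min washout libraries and at 1033 in degrader 30 min replicate 3, against 13.6 and 37.7 in the other libraries of that group, and between 5.23 and 63.2 in every other time-course library used.

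Between 30 min and 1 h of the LBH589 washout, immediate early genes fell, 19 of 34 with 1 rising and 14 not passing (24 past the threshold adjusted over the list alone, median -0.61, adjusted p = 9.22e-07, and adjusted p = 0.344 with an estimated correlation, n = 3 each). Srf, a transcription factor that drives many of them, was at -1.55 ± 0.11, Maff at -1.49 ± 0.17, Fos at -1.40 ± 0.21 and Egr1 at -0.85 ± 0.15, while Nr4a1 rose by 1.21 ± 0.17. Cell cycle genes went the other way, with 13 of 39 higher and 3 lower (19 past the threshold adjusted over the list alone, median 0.16, adjusted p = 0.0359, and adjusted p = 0.344 with an estimated correlation). Lists that also passed downward were heat shock genes (6 of 16 lower, 1 higher, 12 past the threshold adjusted over the list alone, adjusted p = 0.0299, and adjusted p = 0.344 with an estimated correlation) and mast cell and basophil genes (1 of 6 lower, 0 higher, 1 adjusted over the list alone, adjusted p = 0.025, and adjusted p = 0.344 with an estimated correlation). Myc targets did so with 11 of 44 lower and 3 higher (21 past the threshold adjusted over the list alone, adjusted p = 0.025, and adjusted p = 0.678 with an estimated correlation).

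After 30 min of LBH589, 22 of 37 erythroid and heme genes fell and 2 rose (24 past the threshold adjusted over the list alone, median -0.19, adjusted p = 7.42e-06, and adjusted p = 0.102 with an estimated correlation). Myc targets and ribosome biogenesis genes had 30 of 44 lower and 2 higher (33 past the threshold adjusted over the list alone, median -0.16, adjusted p = 1.29e-05, and adjusted p = 0.252 with an estimated correlation). Blood transcription factors had 16 of 24 lower and 4 higher (20 past the threshold adjusted over the list alone, median -0.26, adjusted p = 3.66e-05, and adjusted p = 0.144 with an estimated correlation).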
